A study of Homo sapiens with 2 samples.

How the data were processed

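SNK6 cells, an Epstein-Barr virus-positive human NK/T-cell lymphoma line grown with interleukin-2, were exposed for 72 h to romidepsin, an inhibitor of class I histone deacetylases, with or without sildenafil, a phosphodiesterase inhibitor. Total RNA of each of the 2 samples was amplified with a whole-transcript kit, labelled with biotin and hybridised to an expression array, per the labels' protocols. The samples were assigned from their titles, of which 1 names romidepsin in short form and the other adds a short form of a second drug. The second drug was read as sildenafil because the treatment protocol names no other. Doses are not given in the sources used here, and no untreated or sildenafil-only sample was analysed here.

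The deposited values are a table of log2 signals with 1 column per array and 53617 probe sets. The log base is not written in the table. It was taken as 2 because the deposited signals reach 13.05, above the natural log of a 16-bit scanner's ceiling (11.1) and below its log2 value (16). The summarisation, background correction and normalization that the authors used are not given in the sources used here. The deposited columns had medians of 3.89 (romidepsin) and 3.92 (romidepsin plus sildenafil), were not centred on 0, and when sorted differed nowhere by more than 0.15, so the arrays had been brought to nearly the same distribution. Such processing would remove a change shared by most transcripts, so every difference below is relative to the other transcripts on the array. The table holds no detection calls, spot background or scan batch, so a background level per probe set is unknown, and with 1 array per group any batch and the treatment cannot be told apart. The number of arrays, not a read depth, limits the precision.

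Gene names came from the platform annotation as deposited in GEO, which paired 16098 probe sets with 1 gene symbol and 0 with several. The other 37519 probe sets are unnamed here and entered no gene comparison. All Entrez identifiers matched the current RefSeq gene table, and 0 symbols needed updating. For several gene families no probe set was named, and these are not analysed here. No coordinates are given because no genome build accompanies the values.

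Of the 14884 named genes, 779 had more than 1 probe set, and the probe set with the highest mean of both arrays stood for the gene. A gene was kept when its brighter array reached 3.91, the median of all values of the table, which left 10081 genes. The difference is the log2 signal with sildenafil minus that without. Because each group holds 1 array, no statistical test between the treatments was possible, and no p-value or standard error is given. Genes were counted as higher or lower when the arrays differed by at least 1.5-fold, a rule of size that does not separate an effect of the drug from variation between cultures or arrays.

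For 51 gene lists, the median difference of the members past the filter was placed among the medians of 10000 random lists of equal size matched on mean signal in 10 bins, when at least 5 members remained. A list at or below the 2.5th or at or above the 97.5th percentile is called outer. These percentiles describe the 2 arrays only, treat genes as independent, and would put about 5% of lists in the outer range by chance (6.5% of 200 simulated lists without a shift).

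The lists, the filter, the threshold and the rule for named genes were set before the data were examined. The rule took the 15 largest differences in each direction, leaving out, by symbol, microRNA, small nucleolar, Cajal body and small nuclear RNA genes (with RN7SK, RMRP and RPPH1), provisional LOC or LINC symbols, and Y-linked genes and XIST; vault RNAs were not left out. It then took up to 4 members of each list with the largest absolute difference, and 23 fixed genes of which 14 were named in the annotation. Alternatives changed the filter, the normalization between the arrays (median centring, quantile normalization, lowess centring with a span of 0.3), the handling of several probe sets, the threshold, and the matching and summary of lists. Differences between the arrays were simulated for the 10081 genes with 200 changed genes: the 1.5-fold rule called 95.0% of those changed 2-fold, 100% of those changed 4-fold and 0.921% of the unchanged genes. No replicates existed from which to set the spread of unchanged genes. These rates therefore describe the simulation and are not error rates of the counts below. A simulated list of 20 genes shifted by -0.2 lay at percentile 0.0. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.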

Results

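Whole-transcript expression was measured in SNK6 lymphoma cells after 72 h of romidepsin alone (1 array) or romidepsin together with sildenafil (1 array). The design asked which transcripts differ when sildenafil is added to a histone deacetylase inhibitor. There were no replicates, so no value below carries a replicate error and no difference was tested. The log2 signals ran from 0.93 to 13.05 on the romidepsin array and from 0.79 to 12.97 on the combination array.

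Among the named genes, few differed by 1.5-fold between the arrays. Of 10081 genes past the signal filter, 9880 (98.0%) lay within 1.5-fold between the arrays, 103 were at least 1.5-fold higher with sildenafil and 98 at least 1.5-fold lower. At 2-fold, 9 genes were higher and 9 lower. Among the 17317 probe sets past the filter without a gene name, differences were more frequent and leaned lower, with 626 at least 1.5-fold higher and 1082 lower (9.86% in all). These were counted per probe set, not per gene, and were not matched on signal. Of 454 genes drawn from the pathway and cell type lists, only BBC3 and CCL4 (higher) and ISG20 and STMN2 (lower) lay beyond 1.5-fold. Across the 10081 genes the arrays correlated with r = 0.990, and the central 95% of differences lay between -0.44 and 0.47 on the log2 scale. The SD of the differences fell from 0.34 in the dimmest decile of genes to 0.12 in the brightest decile, so the same fold stands further from the bulk at high signal.

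**Figure D1:**
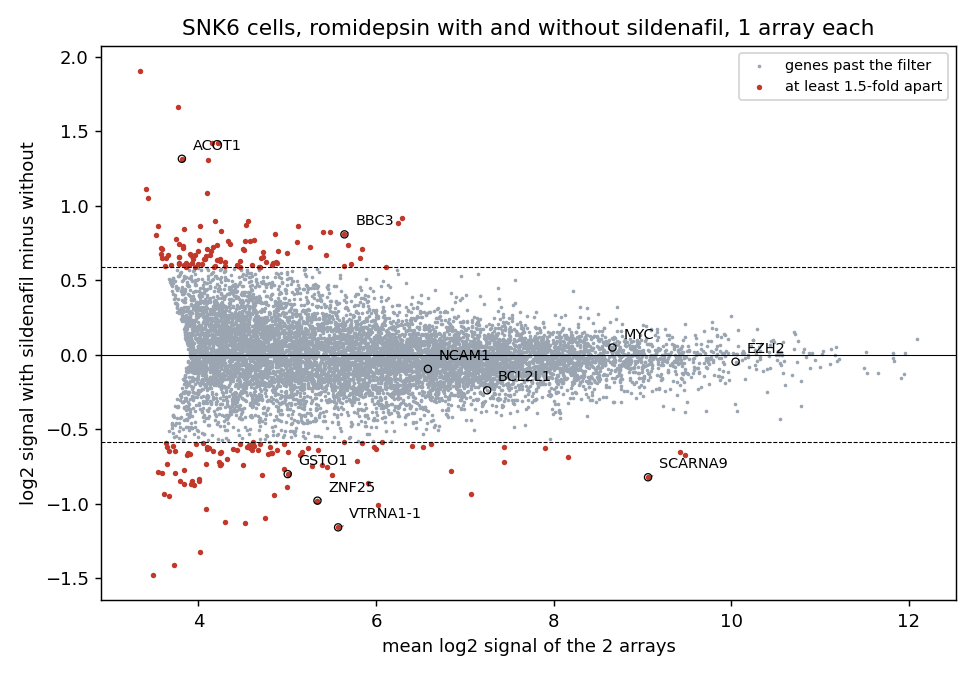
Each point is 1 of the genes past the filter, with the mean log2 signal of the 2 arrays on the x axis and the log2 signal with sildenafil minus that without on the y axis; dashed lines mark 1.5-fold and red points lie beyond it. The 201 red points sit mostly at low signal, while MYC and EZH2 lie close to 0.

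The largest named increases were in genes of low signal. KRTAP5-3 and KRTAP10-1, which encode hair keratin-associated proteins, were 2.68-fold and 2.47-fold higher with sildenafil. ACOT1, a cytosolic acyl-CoA thioesterase, was 2.49-fold higher (log2 signal 3.16 without and 4.47 with sildenafil), and the kallikrein gene KLK12 was 2.16-fold higher. ACOT1 and the keratin-associated genes have near-identical relatives, so their signals may include those of other genes. FBXW10B (2.12-fold), the zinc finger gene ZNF528 (1.87-fold), WFDC12 (1.86-fold), TNFRSF14-AS1 (1.83-fold), FAM86B2-DT (1.82-fold) and PSG4 (1.78-fold) followed. FAM86B2-DT had a second probe set, and the mean of both gave a log2 difference of only 0.23. The genes with a romidepsin signal above 5 in this group were ZNF823 (1.77-fold) and BBC3 (1.75-fold). CPLX1, which encodes the synaptic protein complexin, was 1.75-fold higher, SRD5A3-AS1 1.72-fold and ACTL10 1.70-fold. In 9 of these 15 genes the romidepsin signal lay below the filter level of 3.91.

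Among the largest decreases was VTRNA1-1, a vault RNA, whose signal was 2.23-fold lower with sildenafil (6.15 without and 4.99 with). The pseudogene EFL1P1 was 2.05-fold lower. The zinc finger genes ZNF25 (5.83 without and 4.85 with) and ZNF117 were 1.97-fold and 1.91-fold lower, the antisense transcript DCST1-AS1 1.93-fold and LRRC37B 1.92-fold. GIN1, HYAL6P, KIF9-AS1, RDM1P5, S100A13 and TMEM270 were between 1.78-fold and 1.83-fold lower. S100A13 encodes a calcium-binding protein. GSTO1, an omega-class glutathione transferase, was 1.74-fold lower (5.41 without and 4.61 with). SALL3, a developmental transcription factor, and LCT-AS1 were each 1.74-fold lower. In 10 of these 15 genes the signal with sildenafil lay below 3.91.

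**Figure D2:**
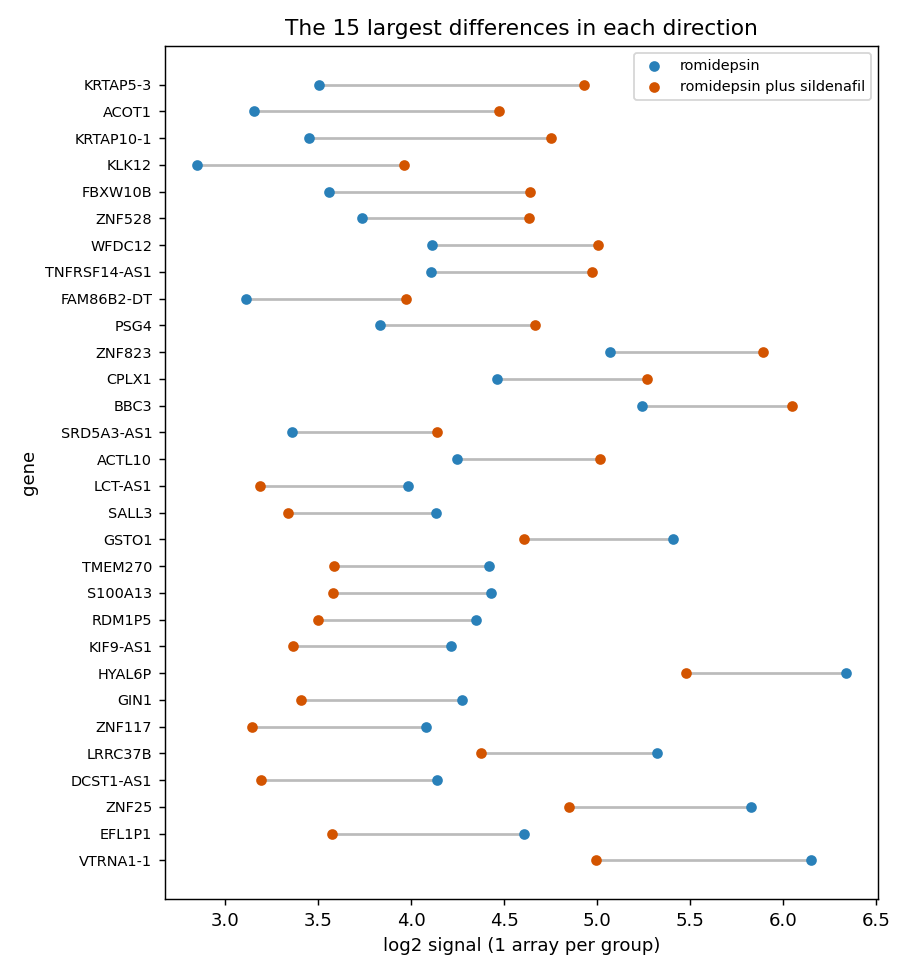
Log2 signal (x axis) of the 15 genes with the largest difference in each direction, with microRNA, small nucleolar, Cajal body and small nuclear RNA genes and provisional symbols left out, and with 1 point per array: blue for romidepsin and orange for romidepsin plus sildenafil. The differences run from -1.16 for VTRNA1-1 to 1.42 for KRTAP5-3, and most of the genes lie below a log2 signal of 6 on both arrays.

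The measured p53 targets had a low median, while BBC3 differed in the opposite direction. Of 29 listed genes 14 were past the filter, and CDKN1A and MDM2 were not among them. The median of the 14 was -0.16, at percentile 0.20 of matched random lists, with 9 members lower and 5 higher. RRM2B, a ribonucleotide reductase subunit, differed by -0.33, TP53I3 by -0.32, SESN2, a stress-induced inhibitor of mTORC1 signalling, by -0.29 and CCNG1, cyclin G1, by -0.28. None of these 4 reached 1.5-fold. The housekeeping genes lay nearly as low, with a median of -0.14 (percentile 3.20). BBC3, which encodes the pro-apoptotic BH3-only protein PUMA, was 0.81 higher (5.24 without and 6.05 with), against an SD of 0.22 among genes of the same signal. In that decile of signal 7 of 1008 genes were at least 1.5-fold higher and 8 lower, and BBC3 rests on 1 probe set. The mean of the list, -0.07, lay at percentile 15.96, inside the range of random lists. Without BBC3 the mean was -0.14, at percentile 1.01. BBC3 was left out after its value was seen, while the random lists kept their own extreme members. That percentile is therefore no support for a lower group.

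Neither the pro-apoptotic BCL2 family nor the anti-apoptotic regulators were outer as a list. The 9 pro-apoptotic members had a median of 0.02 (percentile 71.4), with 5 higher and 4 lower. BBC3 was at 0.81, BID at 0.50, BMF at -0.25 and BAX at -0.16. The 8 anti-apoptotic regulators, not all of them BCL2 family members, had a median of -0.03 (percentile 47.0), with 2 higher and 6 lower. Of the BCL2 family, BCL2A1 differed by -0.45 and BCL2L1, encoding BCL-XL, by -0.24, with MCL1 at -0.06 and BCL2 at -0.00. Among members outside that family, BIRC2 was at -0.31 and XIAP at 0.22. Of the caspases and death receptor genes only 4 members were measured past the filter, with TRADD at 0.31 and APAF1 at 0.10. Of 8 genes listed by name as cyclin-dependent kinase inhibitors, 2 were measured, CDKN2A at 0.20 and CDKN3 at -0.17. CDKN1A was not among them.

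Genes that histone deacetylase inhibitors often induce were slightly lower with sildenafil, with a median of -0.14 over 10 members (percentile 2.07). Of these, 7 were lower and 3 higher, and none reached 1.5-fold. GSN, the actin-severing protein gelsolin, differed by -0.36, TXNIP, an inhibitor of thioredoxin, by -0.31 and SAT1, a polyamine acetyltransferase, by -0.28, while the metallothionein MT1E was at 0.37. TXNIP had a second probe set, and the mean over its probe sets differed by 0.00. The call was lost under most alternatives. Among them were lowess centring (median -0.10, percentile 4.64), unmatched random lists (percentile 2.7) and the mean in place of the median (percentile 11.5). The metallothioneins MT2A and MT1X differed by -0.16 and -0.14, and MT3 by -0.17. Neuronal genes, a class often derepressed by such inhibitors, had a median of -0.03 over 7 members (percentile 21.2). STMN2, which encodes a neuronal microtubule regulator, was at -0.59, the only neuronal gene of the list at least 1.5-fold apart, and RUNDC3A was at 0.44.

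The deacetylase genes, which include the targets of romidepsin, differed little, and PDE5A, which encodes the main target of sildenafil, was not analysed here. The 17 deacetylases and sirtuins had a median of -0.05 (percentile 26.0), with none past 1.5-fold. HDAC1 was at -0.07, HDAC2 at -0.01 and HDAC3 at -0.08, and the largest difference was HDAC6 at -0.23. Of the genes of cGMP signalling 5 were measured past the filter, with a median of 0.05 (percentile 59.3). Their values were -0.25 for PDE9A, which encodes a cGMP-degrading phosphodiesterase, 0.25 for IRAG1, 0.17 for NOS1, 0.05 for NOS3 and 0.04 for VASP. The other phosphodiesterases and cAMP genes had a median of -0.08 over 7 members (percentile 19.1), with ADCY7, an adenylyl cyclase, at 0.46 and PDE7A at -0.27. The drug efflux transporters were not analysed here, nor were the proteasome, the replication-dependent histones, MHC class II and the mitochondrially encoded genes, because no probe set of theirs was named.

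**Figure D3:**
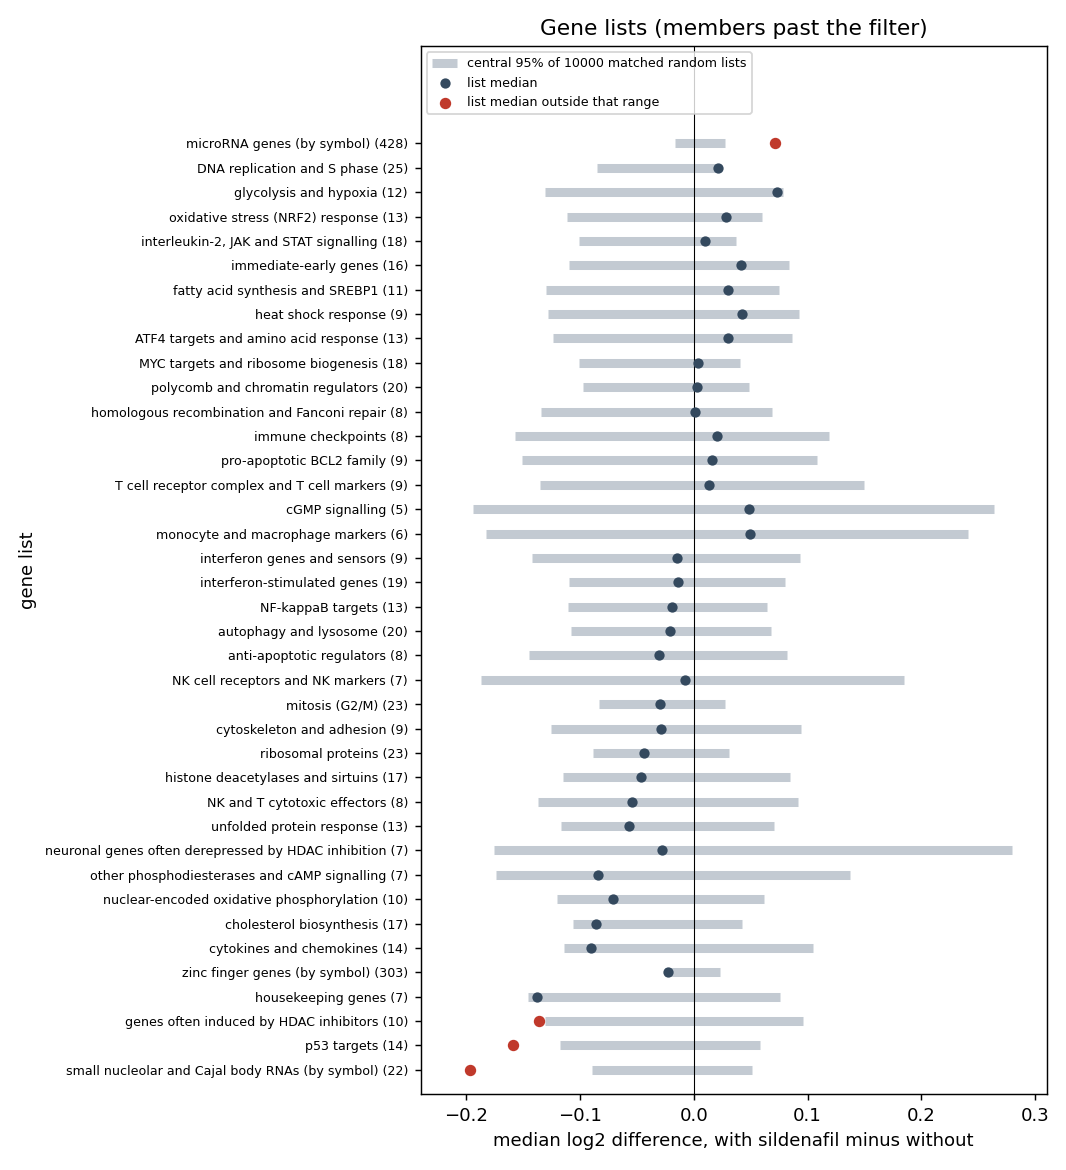
Median log2 difference of each gene list (points, x axis), with the number of members past the filter in parentheses; grey bars span the central 95% of the medians of 10000 random lists matched on size and signal. Of 39 lists, 4 lie outside their bars (red): p53 targets, genes often induced by histone deacetylase inhibitors, and small nucleolar and Cajal body RNAs on the low side, and microRNA genes on the high side.

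Markers of natural killer and T cells were close to equal on the arrays. The cytotoxic effector genes had a median of -0.05 over 8 members (percentile 24.5), and the largest differences were NKG7, a cytotoxic granule protein, at -0.27 and granzyme M (GZMM) at 0.19. The NK receptors and markers had a median of -0.01 over 7 members (percentile 46.6). TBX21, the transcription factor T-bet, was at 0.47, the activating receptor NCR2 at 0.38 and NCAM1 (CD56) at -0.09. The T cell markers had a median of 0.01 over 9 members (percentile 60.1), with CD6 at -0.25 and CD5 at 0.24. Of markers of other cell types, 6 monocyte and macrophage genes had a median of 0.05 (percentile 59.0), with VSIG4 at -0.42 and CSF1R at 0.27. The 4 B cell markers past the filter lay between -0.18 (PAX5) and -0.04 (BLK), and the 3 fibroblast and epithelial markers past it were KRT18 at 0.34, KRT8 at -0.30 and KRT19 at -0.26.

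Immune signalling genes included 2 members beyond 1.5-fold, and none of their lists was outer in the main analysis. Under alternatives, the cytokines and chemokines (only genes with 1 probe set, percentile 0.65) and the immediate-early genes (mean, percentile 98.1) were outer. CCL4, a chemokine gene, was 0.64 higher from a low signal (3.92 without and 4.56 with), while CCL3 was at -0.33 and CCL22 at -0.45. The cytokines and chemokines had a median of -0.09 over 14 members (percentile 5.98), and the NF-kappaB targets of -0.02 over 13 (percentile 50.3). ISG20, an interferon-induced exonuclease, was at -0.62, CXCL10 at -0.37 and IRF7 at 0.30, with a median of -0.01 over 19 interferon-stimulated genes (percentile 50.4). The interferon genes and sensors had a median of -0.01 (percentile 56.3), with TLR3, a receptor for double-stranded RNA, at -0.53 and IRF3 at -0.29. The interleukin-2, JAK and STAT genes had a median of 0.01 over 18 members (percentile 88.3), with SOCS1 at -0.26, PIM3 at 0.25, JAK2 at -0.24 and STAT3 at 0.06. The immune checkpoints had a median of 0.02 over 8 members (percentile 72.9), with LAG3 at 0.29, CD276 at 0.27 and CD274, which encodes PD-L1, at -0.08. The 4 measured MHC class I presentation genes lay between -0.02 and 0.09 (ERAP1 and TAPBP). Immediate-early genes had a median of 0.04 over 16 members (percentile 87.3), with FOSL2 at 0.47, EGR1 at 0.42 and FOSL1 at 0.33.

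Proliferation genes differed little. The 23 mitosis genes had a median of -0.03 (percentile 41.0), with 16 lower and 7 higher, and the largest difference was the phosphatase CDC25C at -0.30. The DNA replication genes had a median of 0.02 over 25 members (percentile 97.1). CCNE2, cyclin E2, was at -0.44, TYMS, thymidylate synthase, at -0.17, and the licensing factor CDT1 at 0.16. Cyclin D genes were at 0.33 (CCND1) and 0.13 (CCND2). The recombination and Fanconi repair genes had a median of 0.00 over 8 members (percentile 73.5), with XRCC3 at -0.25 and PALB2 at -0.18. MYC targets and ribosome biogenesis genes had a median of 0.00 over 18 members (percentile 81.8), and MYC itself was at 0.05. The 23 ribosomal protein genes had a median of -0.04 (percentile 28.7), with RPL32 at -0.45. Chromatin regulators had a median of 0.00 over 20 members (percentile 76.4), with DNMT3B at -0.26, KDM5B at 0.26 and EZH2 at -0.05. The cytoskeleton and adhesion genes had a median of -0.03 over 9 members (percentile 36.3), with S1PR1, a receptor that guides lymphocyte egress, at -0.36.

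Stress and metabolic genes held no member beyond 1.5-fold. The unfolded protein response genes had a median of -0.06 over 13 members (percentile 21.4), with CRELD2 at 0.49 and ATF4 at -0.18. The ATF4 targets had a median of 0.03 over 13 (percentile 83.5), with CTH, cystathionine gamma-lyase, at -0.39 and CBS at 0.32. Heat shock genes had a median of 0.04 over 9 (percentile 86.5), with 8 higher and 1 lower, among them HSPA1L at -0.19, HSPB1 at 0.18 and BAG3 at 0.18. The oxidative stress genes had a median of 0.03 over 13 (percentile 89.6), with GPX1 at -0.32 and HMOX1 at 0.28. Glycolysis and hypoxia genes had a median of 0.07 over 12 (percentile 96.7), with ADM at -0.41, ANKRD37 at 0.38 and GAPDH at -0.26. Oxidative phosphorylation genes had a median of -0.07 over 10 (percentile 14.8), with 9 lower and COX5A at -0.25. The cholesterol biosynthesis genes had a median of -0.09 over 17 (percentile 6.57), with 14 lower and 3 higher. PMVK was at -0.32, EBP at -0.27, MVD at 0.31 and TM7SF2 at 0.32. The fatty acid synthesis genes had a median of 0.03 over 11 (percentile 87.0), with FADS2 at 0.31 and ACLY at 0.21. The autophagy and lysosome genes had a median of -0.02 over 20 (percentile 48.9), with ATG16L1 at -0.48, TFEB, a transcription factor of lysosomal genes, at 0.46 and GABARAPL1 at -0.38. The housekeeping genes had a median of -0.14 over 7 (percentile 3.20), with HPRT1 at -0.33 and PPIA at -0.14.

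Of the small non-coding RNAs, the Cajal body RNAs were lower and the microRNA genes slightly higher than other genes. The list of small nucleolar and Cajal body RNAs, whose named members were all Cajal body RNAs (scaRNAs, guides for the modification of spliceosomal RNAs), had a median of -0.20 over 22 members (percentile 0.01). Of these, 17 were lower with sildenafil, 5 were higher, and 4 were at least 1.5-fold lower. SCARNA1 differed by -1.13, SCARNA9 by -0.82 at a high signal (9.47 without and 8.65 with), SCARNA9L by -0.98 and SCARNA23 by -0.77. SCARNA9 and SCARNA9L are related in sequence, and their signals may not be independent. The microRNA genes, taken by symbol, had a median of 0.07 over 428 members (above all 10000 random lists). Only 418 genes past the filter were classed as microRNA, with a median of 0.08, so the symbol list holds some genes of another class. Of the 428, 29 were at least 1.5-fold lower and 21 higher, among them MIR4266 at 1.90, MIR4731 at 1.66, MIR320B2 at -1.48 and MIR4655 at 1.42. With both of its probe sets averaged, MIR4266 was at 1.47. MIR4267, counted as lower at -0.60, had a second probe set at 1.02. MIR4266, MIR4731 and MIR4655 lay below the filter level without sildenafil (2.39, 2.93 and 3.44), and MIR320B2 with it (2.74). Each passed the filter only on its brighter array, so the size of these differences is uncertain. Among small nuclear and related RNAs, RMRP was at -0.16 and RPPH1 at -0.04. The 303 zinc finger genes had a median of -0.02 (percentile 4.32), with 6 at least 1.5-fold higher and 5 lower.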

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

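The dependence on signal, of single genes and of the p53 list, the yield of short RNAs and the second probe sets filtered on their mean were tested only after the values had been seen; the other tests of this part were set before their results were seen.

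Probe sets without a gene name, which entered none of the comparisons, held more differences than the named genes. Of 17317 unnamed probe sets past the same filter, 626 were at least 1.5-fold higher with sildenafil and 1082 at least 1.5-fold lower, together 9.86%, against 103 and 98 of 10081 named genes. At 2-fold the counts were 128 higher and 345 lower. Among the 6779 unnamed probe sets at or above the median mean signal of the named genes (5.77), 90 were higher and 268 lower. In every decile of named genes above that signal, at most 0.992% lay beyond 1.5-fold. Unnamed probe sets were counted singly, whereas each named gene was counted once by its brightest probe set. What these probe sets measure is not analysed here.

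The named genes beyond 1.5-fold were mostly dim. With genes filtered on the mean of both arrays, 3.32% of the dimmest 3255 genes lay beyond 1.5-fold and 0.277% of the brightest 3254. The ratio was 12, as noise that grows at low signal would give. This filter depends less on the difference itself, though a gene dim on 1 array can still pass it. Of the 201 genes beyond 1.5-fold only 4 had a second probe set with other values and a mean of both arrays past the filter. Turned to the direction of the first, the median difference of these second probe sets was -0.036. They pointed the same way in 1 of the 4 (MIR4518, 0.71 and 0.65). For MIR4267 the 2 probe sets lay in opposite directions (-0.60 and 1.02). So few genes cannot decide on noise of single probe sets. With the second probe set filtered on its brighter array, as first planned, 4 of 7 pointed the same way, but all 4 lay below the filter level without sildenafil. Of these only that of MIR4518, already counted above, also passed on its mean. The others were let in by their own difference, so nothing is read from that count. An effect of sildenafil on these genes remains untested with 1 array per treatment.

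The scaRNAs were lower as a group (median -0.20). Noise of probe sets for short RNAs was examined with microRNA genes as their stand-in. Random lists of 22 microRNA genes reached a median that low in only 0.20% of draws. A lower yield of all short RNAs in 1 extraction may account for the pattern: 11 other short non-coding RNAs (SNAR, vault, RNase P and MRP RNAs) had a median of -0.042, but their bootstrap interval, from -0.29 to 0.01, includes the median of the scaRNAs. The 428 genes with microRNA symbols had a median of 0.07, with 254 higher and 172 lower. That would run against a lower yield of all short RNAs only if their probe sets read short RNAs. Whether they do, and whether their signals lie above background, is unknown. A change of scaRNA levels with sildenafil is another open explanation, and was not tested separately.

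The p53 targets past the filter, 14 of 29 listed genes, had a low median (-0.16) although BBC3 was higher. The housekeeping genes lay nearly as low (-0.14, percentile 3.20). For the median, a signal-dependent difference between the arrays as the whole cause is argued against. Lowess centring moved it to -0.11, at percentile 1.55 among random lists not matched on signal. The mean of the list lay inside the range of random lists (-0.07, percentile 15.96), so the low position itself depends on the summary used. Leaving out each member in turn gave a percentile of at most 0.45, but the middle members lie so close together that the median could hardly move, so that prediction was too weak to decide whether a single member carries the shift. Chance over the lists is open: when differences were shuffled among genes of like signal, 11 of 100 shuffles gave 4 or more outer lists, with a median of 2 and a maximum of 6. The treatment and the array cannot be told apart for this list, because each treatment has 1 array.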

How the results depend on the processing

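The filter on dim genes and the threshold moved the counts most. Without the filter 223 genes were at least 1.5-fold higher and 156 lower, with the filter at the 75th percentile 14 and 28, and at the 2-fold threshold 9 and 9. Among protein-coding genes only, an alternative added after seeing the data, the counts were 65 and 40. Filtering on the mean of both arrays, also added then because the brighter-array filter admits dim genes that differ, gave 75 and 79. Median centring (95 and 103), quantile normalization (93 and 93) and lowess centring (78 and 109) stayed within 1.5 times. The number of outer lists was 3 to 5 over the alternatives, against 4. The list of genes often induced by histone deacetylase inhibitors left the outer range under most alternatives, with medians of -0.1301 (filter at the 75th percentile, mean of all probe sets, and genes with 1 probe set), -0.0841 (quantile normalization), -0.0981 (lowess centring, with matched and, as added after seeing the data, unmatched random lists) and -0.1356 (unmatched random lists), and with a mean of -0.0849; the cause was not tested. The p53 targets left it when the mean (-0.0741) replaced the median. The mean without BBC3, left out after its value was seen, was -0.14 and does not restore the call. The scaRNA and microRNA lists stayed in it under every alternative run. DNA replication genes entered it on the high side under quantile normalization (percentile 99.2) and with single-probe genes (98.7), immediate-early genes with the mean (98.1), zinc finger genes on the low side after lowess centring with unmatched lists (0.51), and cytokines and chemokines on the low side with single-probe genes (0.65). Of 207 named genes under 7 alternatives, none that lay beyond 1.5-fold changed sign. In all, 3 moved by more than the SD of genes of like signal, all when probe sets were averaged (FAM86B2-DT, TXNIP and MIR4266). The filters and the restriction to genes with 1 probe set leave a gene's own difference as it is. Averaging changes only genes with several probe sets. Most of these alternatives could therefore hardly change a sign, and nothing on robustness is read from that. Alternatives for lists drew 2000 random lists, except those with lowess centring, which drew 10000. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Signal over background is unknown, so differences of dim genes cannot be bounded.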

Other observations

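The groupings in this part were chosen after the values had been seen. Counts beyond 1.5-fold by gene class are given without a test and without matching on signal, on which such counts depend, so they do not compare the classes. They were 65 higher with sildenafil and 40 lower of 8749 protein-coding genes past the filter, 13 and 11 of 626 long non-coding RNAs, 21 and 29 of 418 genes classed as microRNA, 4 and 13 of 246 transcribed pseudogenes, and 0 and 4 of 22 genes classed only as non-coding RNA. TERC, the RNA template of telomerase, was at -0.21, and the 8 measured SNAR RNAs, primate-specific small non-coding RNAs, had a median of -0.01.

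The arrays differed slightly with signal. The median difference was 0.07 in the dimmest decile of the filtered genes and -0.02 in the brightest decile, with its lowest value, -0.04, in decile 7.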
